A study of Caenorhabditis elegans with 2 samples.

How the data were processed

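Chromatin immunoprecipitation with sequencing (ChIP-seq) was measured in 2 samples of whole young adult worms, labelled biological replicates 1 and 2 of 1 group. Per the labels, an EGFP tag was inserted with CRISPR aimed at let-526, and an antibody against GFP was used on sonicated chromatin. The labels name a possible control experiment, which was not analysed here.

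The deposited files were lists of peaks on the ce11 assembly, made by the authors for each replicate and for both together. Each peak has a deposited signal, the peak caller's own value, which cannot be compared between lists of different depth. Each also has a deposited score of at most 1000, which was checked against the irreproducible discovery rate (IDR) in the ranked lists. The IDR is given by the authors as −log10, and the lowest score in the thresholded lists was 830, near an IDR of 0.01. The peak caller, the aligner and their versions are not given in the sources used here. The ranked lists held 81275, 78700, 46104 and 49296 peaks, for the optimal and conservative comparisons and for replicates 1 and 2. Of the ranked lists of the whole series, the one holding every conservative peak was taken as replicate against replicate, and the one holding every optimal peak as the other. The files hold no read counts, so depth is unknown, and no interval or limit on depth was computed. Every signal and score column used was matched to its sample or to the pooled samples, with 0 unmatched.

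Positions were compared with the WBcel235 genome and Ensembl release 115 genes, of which 19973 protein-coding genes on I to V and X were used. A gene had a promoter peak when a summit lay from 1000 bp upstream to 200 bp downstream of its annotated start. Each other summit was placed in the first that applied of coding exon, 5' UTR, 3' UTR, intron and intergenic sequence. Chance was taken from 100000 rotations of all peaks round each chromosome, which keep their spacing (permutation test, two-sided except for overlap between replicates). Overlap was 1 bp or more. Shares of X and of the central 33.3% of autosomes were tested with exact binomial tests, and gene lists and motifs with two-sided Fisher's exact tests. Benjamini-Hochberg adjustment was made over 27 lists, 10 motifs, 5 locations outside promoter windows or 9 lists with 5 or more promoter peaks, with a threshold of 0.05. GC content was compared by sign-flip permutation of each summit against the mean of its flanks. Calls over the 27 lists were 8 with more and 4 with fewer promoter peaks than other genes, and 12 passed at an unadjusted p below the same threshold.

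The lists, the motifs, the tests and most of the other settings tried were chosen before the data were examined. The lists were SWI/SNF subunits, other chromatin regulators, cytosolic ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, proteasome subunits, oxidative phosphorylation, splicing factors, histones, heat shock and chaperones, homeobox genes, nuclear hormone receptors, Wnt pathway, insulin pathway, cell cycle and DNA replication, germline and oocyte, sperm, intestine, body wall muscle, pharynx, neurons, epidermis and cuticle, somatic gonad with vulva and uterus, chemoreceptors, F-box and MATH proteins, C-type lectins, and neuropeptides with insulin-like peptides. Named genes were, by a rule set in advance, let-526 and the other SWI/SNF subunits, the nearest start to each of the 20 strongest optimal peaks, and up to 4 members of each list with the strongest promoter peak. Genes named in the last part of the closing section were chosen after their values were seen, as were pairs of genes sharing a peak, such as cct-1.

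The alternatives were the conservative peaks, each replicate alone, peaks above the median signal, other windows, distances, overlap rules and backgrounds, the nearest start only, and 10000 rotations in place of Fisher's test. Rotation was scored by a list's share of all genes with a peak. Its first implementation scored the number of genes, and both are reported. Calls were also shifted along the gene order of each chromosome, which keeps their number and their runs, and genes were compared within strata of promoter GC content and motifs, which were chosen after the data were seen. So were the shares of other locations among summits outside promoter windows, with both counts taken from the same rotations, because shares of all summits fall when the promoter share rises. No paired comparison of samples was possible because there was 1 group. Fisher's tests of motifs treated summit and flank windows as independent, although each summit has flanks of its own. Several of the tests were tried on simulated data with known answers. In 40 runs each, planted promoter shares, overlaps, correlations and list differences were called in 40, and a planted difference in median signal in 39. With nothing planted, calls were made in 0 to 2 of 40 runs, and for motifs in 1 of 20 runs. Simulated peaks and gene calls were drawn independently, so these runs do not give the rate of false calls where peaks cluster or genes share a peak. The rotation of lists, the strata, the shares outside promoter windows and the binomial tests were not simulated. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.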

Results

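Binding of LET-526 was measured by ChIP-seq in whole young adult Caenorhabditis elegans. LET-526 is the worm ortholog of ARID1, a DNA-binding subunit of the SWI/SNF (BAF) complex, which moves nucleosomes. The worms carried an EGFP tag inserted at let-526 with CRISPR, and chromatin was recovered with an antibody against GFP. There was 1 group with 2 biological replicates, collected at 60 hours, and no control library was analysed here. The files gave peaks and not reads, so the depth of each library is unknown. Intervals are exact Clopper-Pearson 95% intervals, which cover counting error over peaks or genes only. For a count of 0, the limit given is 3 divided by the number of genes, an approximate one-sided 95% limit. All positions are on the ce11 assembly (WBcel235).

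The first comparison asked how far the replicates matched. Replicate 1 had 585 thresholded peaks and replicate 2 had 421. Of the peaks of replicate 1, 277 (47.4%, interval 43.2 to 51.5%) overlapped a peak of replicate 2, against 0.211% when the peaks were rotated round their chromosomes. Of the peaks of replicate 2, 271 (64.4%, interval 59.6 to 69.0%) overlapped a peak of replicate 1, against 0.286%. Each one-sided permutation p was 1.00e-05, the smallest possible. The optimal list, made from both replicates, held 1200 peaks and the stricter conservative list held 1077, with 907 identical peaks in both. The optimal list held 544 of the replicate 1 peaks (93.0%) and 392 of the replicate 2 peaks (93.1%). Of its own peaks, 273 (22.8%) were called in both replicates and 520 (43.3%) in neither. The 520 peaks had a median signal of 80.4, against 153.5 for the 273. Over 1170 optimal peaks found in the ranked lists of both replicates, signals had a Spearman rho of 0.364 and a Pearson r of 0.503 on the log10 scale (each two-sided permutation p = 1.00e-05, the smallest possible). This correlation is across peaks, which are not independent replicates, and 46 of the 1200 peaks (3.83%) overlapped a stronger optimal peak, so some sites counted more than once. Without such peaks, rho was 0.370 over 1127 peaks (permutation p = 1.00e-05).

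**Figure D1:**
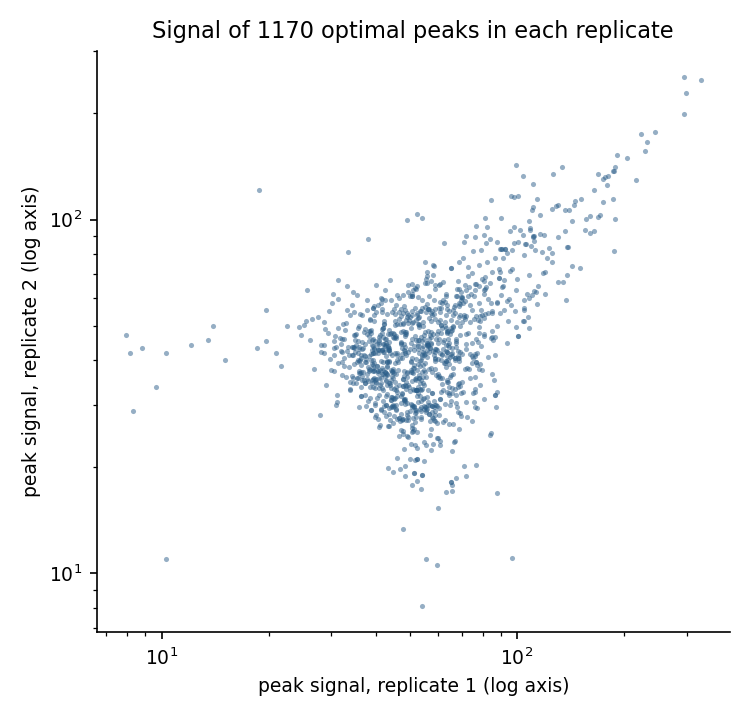
Peak signal in replicate 1 (x axis) and replicate 2 (y axis), both on log scales in the peak caller's own unit, for the 1170 optimal peaks found in both ranked lists. Each point is a peak, and the Spearman rho across peaks was 0.364.

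The strongest peak of the optimal list lay upstream of tasp-1, which encodes a threonine aspartase that cleaves nuclear proteins (WBGene00010480, III 10759139 to 10759370, signal 588.6). Its signal was 329.4 in replicate 1 and 248.7 in replicate 2, and its summit was 49 bp upstream of the annotated start. The next peaks of that list lay upstream of rpl-3, a ribosomal protein gene (signal 551.3), mog-4, which encodes an RNA helicase of the spliceosome (522.6), and F44E5.4, which encodes an Hsp70 family chaperone (496.2). The peak upstream of rpa-2, which encodes a subunit of the single-strand DNA-binding protein RPA, had a signal of 409. Among the 20 strongest peaks of the list, 15 lay in a promoter window, 4 between genes and 1 in an intron, and all 20 were called in both replicates. The list left out 124 peaks that passed the authors' reproducibility threshold, among them 14 of the 20 strongest such peaks, with signals up to 3308, and only 2.42% of the 124 lay in promoter windows. The intronic peak was in epg-9, an autophagy gene. The intergenic peaks had fbxa-190 (an F-box gene), K08F11.1 (nearest to 2 of the peaks) and K07D4.2 as their nearest starts. The others in promoter windows were nearest to Y17G9B.5 (whose peak also lay in the window of rpl-20), rpl-15, rpl-35, K12H4.5, F59C6.18, mtcu-2, Y62F5A.12, cnk-1, tag-340 and cdc-48.1. Of these, mtcu-2 encodes a mitochondrial tRNA-modifying enzyme, cnk-1 a Ras-pathway scaffold and cdc-48.1 an ATPase that unfolds ubiquitinated proteins. The summit nearest to mtcu-2 also lay within another gene, let-268.

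Promoters held more peaks than chance. Of the 1200 optimal summits, 522 (43.5%, interval 40.7 to 46.4%) lay between 1000 bp upstream and 200 bp downstream of a protein-coding gene's start. Rotated peaks gave 21.2% (SD 1.24), a ratio of 2.05 (two-sided permutation p = 2.00e-05, the smallest possible). The share was 46.5% in replicate 1 and 47.3% in replicate 2. Upstream of the nearest start lay 456 of the 522 summits, with a median position of −234 bp. The other locations were then compared among the 678 summits outside the windows, a comparison chosen after the data were seen. Coding exons held 59 of the 678 (8.70%, interval 6.69 to 11.1%) against 25.4% for rotated peaks, and intergenic sequence held 315 (46.5%, interval 42.7 to 50.3%) against 31.7% (each two-sided permutation p = 2.00e-05, the smallest possible). The 5' UTRs held 2.21% against 0.712% (permutation p = 4.00e-05, adjusted p = 6.67e-05 over 5 locations). Introns held 40.6% against 39.1% (permutation p = 0.397) and 3' UTRs 2.06% against 3.06% (p = 0.0672), neither a detectable difference. In replicates 1 and 2, coding exons held 7.67 and 5.41% and intergenic sequence 51.1 and 54.5%. A distance over 2000 bp to the nearest start was found for 377 peaks.

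**Figure D2:**
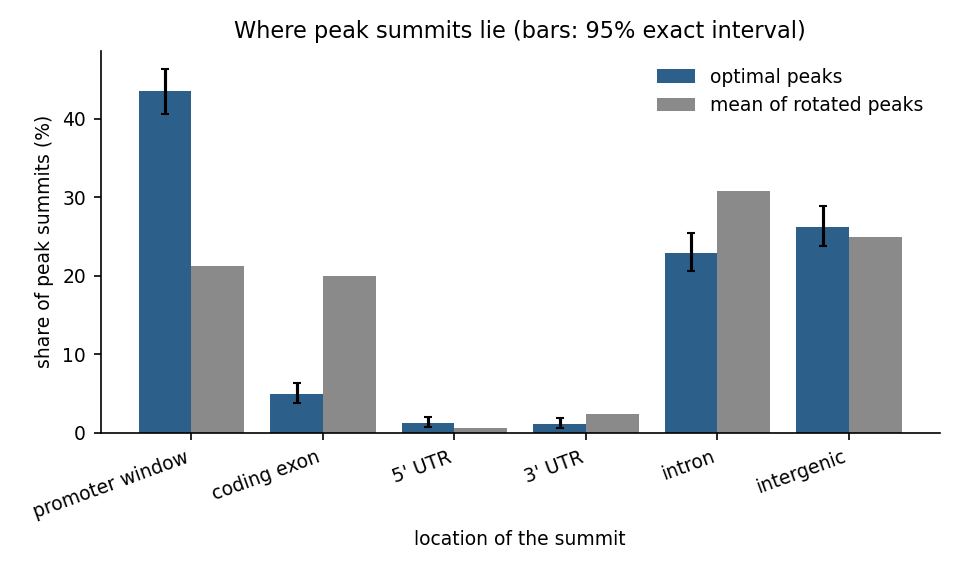
Share of optimal peak summits in each annotated location (y axis, percent; blue, with exact 95% intervals) beside the mean share of rotated peaks (grey). Promoter windows held 43.5% of summits against 21.2% for rotated peaks, an excess that lowers the shares of the other locations.

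Ribosomal protein, chaperone and translation factor genes carried promoter peaks more often than other genes. A promoter peak was found for 664 of 19973 protein-coding genes (3.32%). Cytosolic ribosomal protein genes had one in 21 of 81 members (25.9%, interval 16.8 to 36.9%) against 3.23% of other genes (adjusted exact p = 1.88e-12), led by rpl-3, rpl-20 (387.4), rpl-15 (356.6) and rpl-35 (347.4). Chaperone genes had one in 13 of 60 (21.7%, adjusted exact p = 5.95e-07), led by hsp-1, the constitutive Hsc70 (286), dnj-13, its DnaJ cofactor (268.2), cct-8 of the cytosolic chaperonin (237.9) and hsp-3, an endoplasmic reticulum Hsp70 (180.9). Translation factor genes had one in 9 of 42 (21.4%, adjusted exact p = 4.23e-05), led by iff-2, which encodes eIF5A (222.3), and the elongation factor genes eef-2 (182.6), eef-1G (145.2) and eef-1A.2 (139). These p values are from two-sided Fisher's exact tests, adjusted over 27 lists. The 3 lists passed in each replicate alone, with 18 and 17 ribosomal, 11 and 5 chaperone, and 6 and 5 translation factor genes in replicates 1 and 2. When each peak was given to its nearest start only, ribosomal genes fell to 12 of 81 (14.8%, adjusted exact p = 1.13e-05), chaperones to 6 of 60 (10%, 0.0177) and translation factors to 8 of 42 (19.1%, 7.65e-05).

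Chromatin regulators outside SWI/SNF had promoter peaks in 10 of 42 members (23.8%, interval 12.1 to 39.4%, adjusted exact p = 5.85e-06), with 9 in replicate 1 and 5 in replicate 2, and in 5 of 42 (11.9%, adjusted exact p = 0.0177) when each peak was given to its nearest start only. The strongest were at cbp-1, which encodes the CBP/p300 acetyltransferase (293.8), and set-16, which encodes an MLL-type histone H3 lysine methyltransferase (244.2). Peaks also lay at set-2, which encodes a SET1-type methyltransferase (142.2), and lin-53, which encodes a histone-binding RbAp48 protein (120.5). Oxidative phosphorylation genes had a peak in 6 of 38 (15.8%, adjusted exact p = 0.00464), led by cox-5A (242) and cox-5B (204) of cytochrome oxidase and atp-5 (178.9) and atp-1 (164.8) of ATP synthase. Splicing factor genes had a peak in 7 of 45 (15.6%, adjusted exact p = 0.00282), led by prp-19 (221.1), the SR protein genes rsp-1 and rsp-2, which share a peak (121.5), and rsp-6 (109.2). Splicing did not pass in replicate 2 alone (3 genes, adjusted exact p = 0.0763) or with the nearest start only (3 genes, adjusted exact p = 0.216). Histones did not pass with the nearest start only either (5 genes, adjusted exact p = 0.121). Insulin pathway genes had a peak in 3 of 16 (18.8%, adjusted exact p = 0.0388), which were ftt-2, a 14-3-3 gene (108.6), daf-16, which encodes the FOXO factor (88.1), and skn-1, which encodes an Nrf-like factor (76.9). Histone genes had a peak in 7 of 81 (8.64%, adjusted exact p = 0.0408), led by his-37 (109.1), hil-4 (84.8), and his-35 and his-41, which share a peak (83.1). The insulin and histone lists did not pass in either replicate alone, and 158 of the 522 promoter peaks (30.3%) lay in the windows of 2 or more genes. Rotating the peaks in place of Fisher's test ended the calls of the oxidative phosphorylation and insulin (each adjusted permutation p = 0.146), splicing (0.172) and histone (0.4997) lists, although the shares expected from rotation, scaled to 664 genes, were 2.99 to 3.47%. Rotated peaks reached only 267.5 genes on average, so the unscaled expected counts of these lists were 0.214 to 0.978 genes. When calls were shifted along the gene order, oxidative phosphorylation (adjusted permutation p = 0.0108) and splicing (0.0115) passed, and insulin (0.0638) and histones (0.113) did not.

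Chemoreceptor, F-box and MATH, C-type lectin and neuropeptide genes carried promoter peaks less often than other genes. Chemoreceptor genes had one in 5 of 1364 (0.367%, interval 0.119 to 0.853%) against 3.54% of other genes (adjusted exact p = 3.15e-13), with 2 in replicate 1 and 3 in replicate 2. The strongest were at srh-269 (146.4), sri-5 (122.3), sre-23 (110) and srh-2 (77.9), which belong to families of predicted odorant receptors. F-box and MATH genes had one in 3 of 395 (0.760%, adjusted exact p = 0.00464), at math-33 (93.8), fbxa-24 and fbxb-72. This list had 0 of 395 in each replicate alone and still passed (adjusted exact p = 0.00392 in replicate 1 and 0.0282 in replicate 2). C-type lectin genes had none in 240, which allows up to 1.25% (adjusted exact p = 0.00282). Neuropeptide and insulin-like peptide genes had none in 140, which allows up to 2.14% (adjusted exact p = 0.0388). The lectin and neuropeptide lists did not pass in either replicate alone, and neuropeptides did not pass with the nearest start only (adjusted exact p = 0.121). Rotation ended the calls of the F-box (adjusted permutation p = 0.214), lectin (0.338) and neuropeptide (0.607) lists, although the shares expected from rotation, scaled to 664 genes, were 3.10 to 3.48%. Rotated peaks reached only 267.5 genes on average, and the unscaled expected counts were 5.46, 3.00 and 1.96 genes. With 0 genes seen, rotation could not have called the lectin and neuropeptide lists. The F-box, lectin and neuropeptide lists all passed when calls were shifted along the gene order (adjusted permutation p = 0.0276, 0.0108 and 0.0470).

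**Figure D3:**
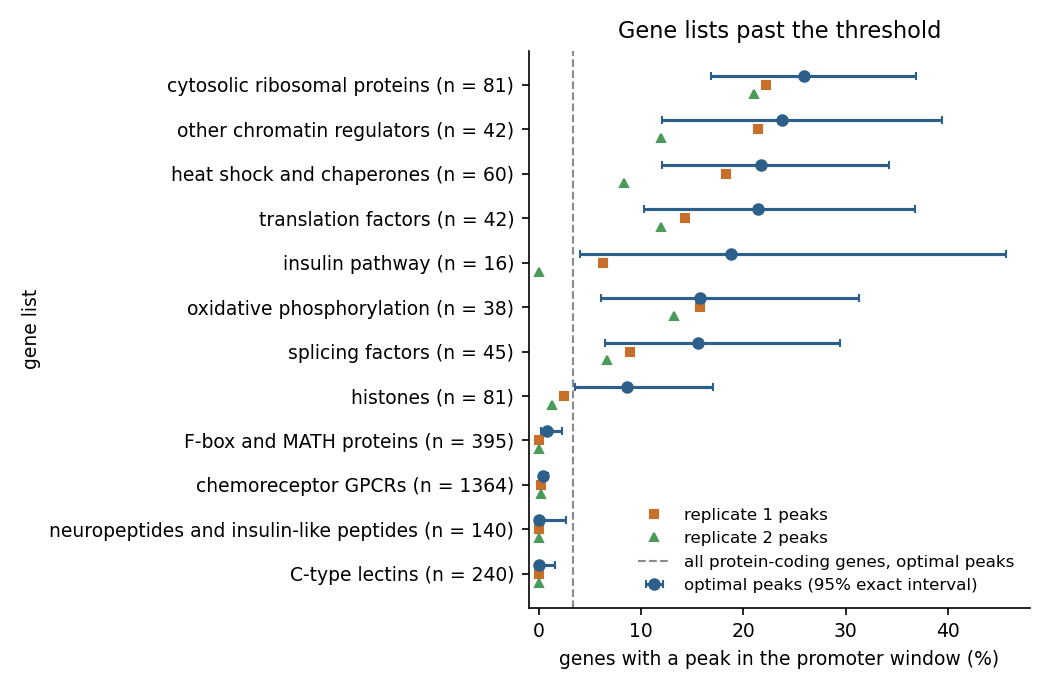
Share of genes with a promoter peak (x axis, percent) in the 12 lists that differed from other genes, for optimal peaks (circles, with exact 95% intervals), replicate 1 (squares) and replicate 2 (triangles). Ribosomal proteins stood highest at 25.9%, against 3.32% of all protein-coding genes (dashed line).

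Lists of tissue genes did not pass with the optimal peaks, although epidermis genes did in some alternatives. Germline and oocyte genes had a promoter peak in 3 of 60, at ego-1, an RNA-dependent RNA polymerase gene (161.2), mex-1, a zinc-finger gene of oocytes and embryos (145), and cgh-1, a DEAD-box helicase gene (103.5). Intestinal genes had 2 of 47, the yolk protein genes vit-2 (115.4) and vit-6 (88.5). Body wall muscle genes had 2 of 45, unc-60, which encodes cofilin, and unc-112, which encodes kindlin. Neuronal genes had 1 of 67, syd-2, which encodes a liprin of presynaptic sites. Epidermis and cuticle genes had 4 of 280, grl-26, grl-7 and the collagen genes col-71 and col-85. They were fewer than other genes with conservative peaks (1 of 280, adjusted exact p = 0.00936), without peaks near tRNA genes (2 of 280, 0.0324) and against named genes only (4 of 280, 0.0361). The gonad, vulva and uterus list had 1 of 48, the fibroblast growth factor gene egl-17. Sperm genes had none in 86, which allows up to 3.49%, and pharyngeal genes none in 27, which allows up to 11.1%. Homeobox genes had 3 of 91 (ceh-38, ceh-99 and ceh-39), and nuclear hormone receptor genes had 5 of 274, led by nhr-48 (129.4), nhr-35, nhr-142 and nhr-47. Wnt pathway genes had 1 of 25, the Dishevelled gene mig-5 (103.5), whose peak also lay in the window of cct-1. Cell cycle and replication genes had 1 of 37, pcn-1, which encodes the sliding clamp PCNA (144.8). Aminoacyl-tRNA synthetase genes had 2 of 32, ears-2 and aars-1, and proteasome genes had 2 of 33, rpn-3 (132.5) and rpn-9. The adjusted exact p was 0.14 or higher for each of the 15 lists without a difference. In replicate 1 alone, nuclear hormone receptor and epidermis genes had none and were fewer than other genes (each adjusted exact p = 0.0301).

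Among SWI/SNF genes, the share with a promoter peak did not differ detectably from other genes. Of 13 subunit genes, 2 had one (15.4%, interval 1.92 to 45.5%, against 3.32% of other genes, adjusted exact p = 0.14), swsn-7, which encodes an ARID2-like subunit (signal 149.9, 84.4 in replicate 1 and 58.2 in replicate 2), and swsn-3, which encodes an HMG-box subunit (74.1, 37.0 and 43.3). The swsn-7 peak was called in both replicates and the swsn-3 peak in neither. At let-526 itself (WBGene00002717, I 5300852 to 5317392), 3 optimal peaks lay in introns, 808, 1016 and 5545 bp downstream of the start, with signals of 24.6, 89.2 and 83.1. None of the 3 was called in either replicate, and the pair nearest the start matched a single peak of the unthresholded ranked list of replicate 2. An intronic peak also lay in pbrm-1, which encodes polybromo (98.7), 5033 bp from the start. No optimal summit lay in the window or body of swsn-1, swsn-2.2, swsn-4, swsn-6, swsn-9, snfc-5, phf-10, dpff-1 or ham-3.

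Peaks at ribosomal protein promoters were also stronger. Their median signal was 171.5, against 96.1 for other promoter peaks, a ratio of 1.79 (two-sided permutation test, adjusted p = 9.00e-05 over 9 lists, the smallest possible). Oxidative phosphorylation peaks had a median of 164.8 against 97.1, a ratio of 1.70 (adjusted permutation p = 0.0237). Chaperone peaks had a median of 130.7 against 97.1, a ratio of 1.35 (adjusted permutation p = 0.0347), which did not pass with conservative peaks (ratio 1.26, adjusted p = 0.0713).

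Transfer RNA genes held many more peaks than chance. Within 200 bp of a tRNA gene lay 135 summits (11.3%, interval 9.52 to 13.2%) against 0.291% for rotated peaks, a ratio of 38.7 (two-sided permutation p = 2.00e-05, the smallest possible). The share was 9.74% in replicate 1 and 12.8% in replicate 2, and 147 of 612 tRNA genes had a peak. None of the 20 strongest peaks of the optimal list was near a tRNA gene, but the median signal near tRNA genes was 92.5, against 92.3 for other peaks. Small nucleolar RNA genes, whose products guide RNA modification, had 4.33% of summits against 0.183%, with 4.62% in replicate 1 and 8.08% in replicate 2. Small nuclear RNA genes of the splicing machinery had 1.0% against 0.0596%, with 1.54% in replicate 1 and 1.66% in replicate 2. For the optimal peaks, each permutation p was 2.00e-05. MicroRNA genes had 0.583% against 0.121% (permutation p = 0.00288), which did not pass in replicate 2 alone (p = 0.198). Other ncRNA genes had 244 summits (20.3%) against 3.59% (permutation p = 2.00e-05), of which 87 were also near a tRNA gene. No control library was analysed here. Recovery of these noncoding RNA genes whatever the tagged protein therefore cannot be told apart from binding of LET-526.

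The X chromosome held 253 peaks (21.1%, interval 18.8 to 23.5%), against 17.7% of the genome's length (two-sided exact binomial p = 0.00244) and 13.7% of protein-coding genes (p = 2.27e-12). Against length the share did not pass in replicate 1 (19.3%, exact p = 0.303) or replicate 2 (20.2%, p = 0.18). Of the tRNA genes, 276 (45.1%) are on X, and 65 of the 135 tRNA peaks were there. Without peaks near tRNA genes, 188 of 1065 peaks were on X (17.7%, exact p = 1). On the autosomes, the central 33.3% of each chromosome, which is rich in conserved genes, held 402 of 947 peaks (42.5%, interval 39.3 to 45.7%, exact p = 5.17e-09), and 38.1% of protein-coding genes (p = 0.00670).

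Sequence at summits was richer in G and C than its surroundings. The GC content within 100 bp of the summit was 45.5%, against 37.1% in windows 1000 bp to each side, a difference of 8.42 points (SE 0.252, 1200 peaks, two-sided sign-flip permutation p = 1.00e-05, the smallest possible). GAGAGA, the site type of GAGA-like factors, was found at 34.3% of summits against 11.4% of flanks (adjusted Fisher p = 6.07e-57). CTGCGTCT, a frequent worm promoter element, was found at 11.8% against 1.5% (8.11e-38), and GTGTGT at 20% against 7.33% (6.62e-27). CGCGCG was found at 7.83% against 1.29% (6.06e-22), and GGGCGG, the Sp1 type, at 11.6% against 3.79% (7.33e-18). CACGTG, the E-box of basic helix-loop-helix factors, was found at 10.3% against 4.50%, and TTTCGCG, an E2F type, at 5.67% against 2.75%. TGATAA, the GATA type, was rarer at summits (13.7% against 19.2%), as was TATAAA, the TATA box (11.3% against 18.4%), which did not pass in replicate 2 alone (13.5% against 17.8%, adjusted Fisher's exact p = 0.0594). TGACTCA, the AP-1 type, did not differ (1.92% against 1.54%, adjusted Fisher's exact p = 0.410), although it passed in replicate 1 alone (2.74% against 1.11%, adjusted p = 0.0162). With promoters that had no peak as the background, odds ratios fell from 8.74 to 4.83 for CTGCGTCT, 6.50 to 3.92 for CGCGCG and 3.32 to 2.06 for GGGCGG. That of TATAAA went from 0.566 to 0.289, and all still passed. This background was the 200 bp just upstream of starts, and TATAAA was in 30.7% of its windows. All 1200 summits were set against it, 678 of them outside promoter windows, so a difference of location is part of these odds ratios. With peaks above the median signal, the odds ratio of TTTCGCG rose from 2.12 to 4.75. No motif test allowed for the higher GC content of summits. Base composition therefore cannot be told apart as a cause of more CGCGCG, GGGCGG, CACGTG, CTGCGTCT and TTTCGCG or less TGATAA and TATAAA.

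**Figure D4:**
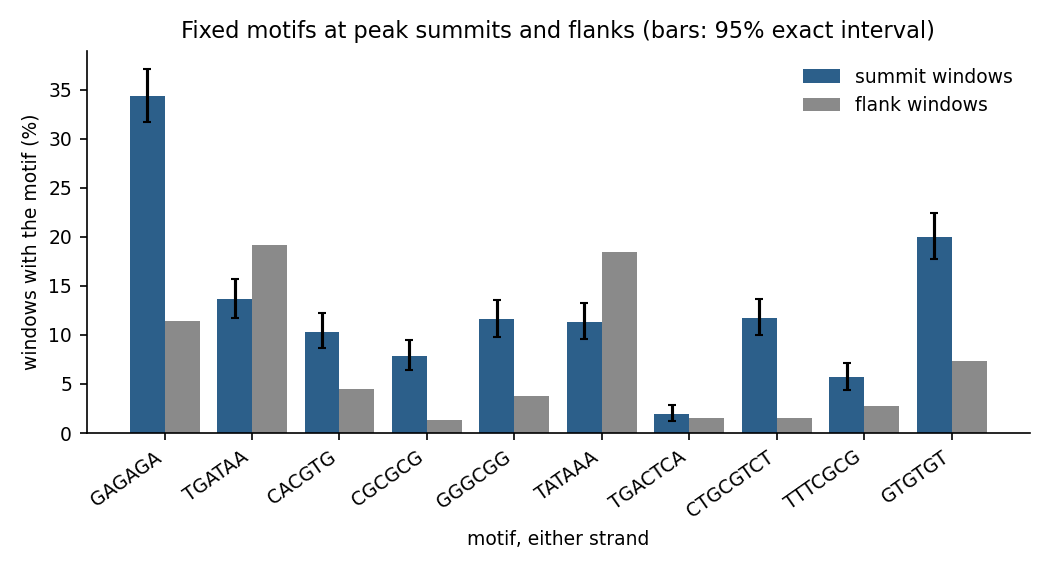
Share of optimal summits with each fixed motif within 100 bp (y axis, percent; blue, with exact 95% intervals) beside the share of flank windows (grey). GAGAGA was found at 34.3% of summits against 11.4% of flanks.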

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

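The tests of the yolk protein genes, of the gene-order shift, of single lists under rotation and shift together, of promoter strata and of X without peaks near tRNA genes were chosen only after the data were seen.

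The ranked lists held peaks past the authors' IDR threshold that the thresholded lists did not hold, a signal in data that the comparisons did not use: 124 for the optimal list (9.37%), 115 for the conservative list, 65 for replicate 1 and 110 for replicate 2 (20.7%). They included 14 of the 20 strongest peaks past the threshold, led by one on X at 15810950 to 15811192 with a signal of 3308, and 2.42% of the 124 lay in promoter windows against 43.5% of kept peaks. GAGAGA at 7.26% of the 124 summits, against 34.3% of kept summits (two-sided Fisher's exact test, p = 1.18e-11), argued against sites of the same sequence class as the kept peaks. Repeat-masked sequence, which held 84.7% of the 124 summits against 15.9% of kept summits, and a fixed set of regions left out, since 0% of the 414 absent peaks overlapped a kept peak of any list, both remain candidate explanations. The labels do not state the content of a further parent file of the thresholded lists, and no biological explanation was tested.

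Of the 27 gene lists, 12 differed from other genes, and within strata of promoter GC content and of GAGAGA and CTGCGTCT presence 10 of the 12 passed in the same direction, which argued against promoter composition as the whole cause. The histone call ended because more genes were expected (5.06 against 7 seen, odds ratio 2.77 before and 1.43 after), and the neuropeptide call ended with 4.89 expected against 0 seen. In a prediction written before this check, clusters of neighbouring genes would leave most of the called lists not passing under rotation. Scored by share of all genes with a peak, 5 of 12 passed, so that prediction was met. Scored by number of genes, as first implemented, 9 of 12 passed, which did not meet it. These scorings disagreed, so the prediction did not settle the question. A later rule, set after the data were seen, asked whether any list passed both rotation and the gene-order shift. The ribosomal, chaperone, chromatin regulator, translation factor and chemoreceptor lists (5) passed both. For these lists only, this argued against such clusters as the whole cause. By the same rule such clusters cannot be told apart as a cause for the other 7 lists. None of the 7 passed under rotation, but rotated peaks reached 267.5 genes on average against 664 seen. Failing there therefore says little about clusters. Lectins and neuropeptides could not have passed, since 0 genes is the lowest count (permutation p = 0.125 and 0.292 before adjustment). The shift, which keeps the number of calls and their runs, was passed by 5 of the 7, and not by insulin and histones. Recovery of highly transcribed loci whatever the tagged protein may contribute and cannot be told apart either, since 2 of the 6 yolk protein genes had a promoter peak and no control library was analysed here, and no biological explanation was tested.

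The share of peaks on X was above its share of length (21.1% against 17.7%). Without peaks near tRNA genes it was 17.7% (interval 15.4 to 20.1%, two-sided exact binomial p = 1). The many tRNA genes on X are a candidate explanation of the excess over length. No biological explanation was tested.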

How the results depend on the processing

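The strata, the gene-order shift, the number of genes under rotation, the tests without peaks near tRNA genes, those with absent peaks put back, the correlation without overlapping peaks, the shares among summits outside promoter windows and the repeats of peak counts and locations were chosen only after the data were seen. Of 68 repeats of the leading results, 61 kept their direction and side of the threshold or stayed within the tolerance for counts, 2 no longer passed, 4 counts moved by more than 1.5 times and 1 reversed. Among 351 repeats of single lists, motifs and locations, 295 were the same, 41 no longer passed, 6 newly passed and 9 reversed.

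Leaving out a replicate gave 421 to 585 peaks, 19.3 to 20.2% of peaks on X (no longer passing) and 7 to 10 lists past the threshold. Fewer peaks follow from how these alternatives are built, and for X the cause was not tested. Without peaks near tRNA genes, 17.7% of peaks were on X, just below its share of length. Rotation of peaks in place of Fisher's test left 5 of 12 lists, and 9 when scored by number of genes.

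The other reversals were of small counts or small differences, and the cause was not tested. Intergenic peaks were 24.7% of all conservative summits, below the rotated share, but 45.9% of those outside promoter windows, above it. Outside the windows, leaving out a replicate gave 35.1 to 37.7% in introns, below the rotated share. Leaving out a replicate gave 1.24 to 2.47% of histones and 0 to 6.25% of the insulin pathway, both reversed without replicate 1, and peaks above the median signal gave 1.24% of histones. The odds ratio of TGACTCA was 0.751 against promoters without a peak. Under rotation scored by number of genes, nuclear hormone receptors (1.82%) and epidermis (1.43%) lay above the rotated share, but rotated peaks reached 267.5 genes against 664, so that scoring carries the overall promoter excess by construction. Depth is unknown, so how many weaker peaks it hid cannot be given.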

Other observations

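The families and their repeat without members of the fixed lists were tested only after the data were seen, and the genes named here were chosen after their values were seen. Families were taken from gene symbols, with 15 or more members of which fewer than 50% were in a fixed list. When members of the fixed lists were left out, 3 of the 73 families had more promoter peaks than other genes outside those lists and 0 had fewer. The sec family, which includes genes of protein translocation and of vesicle transport, had 5 of 19 (26.3%, two-sided Fisher's exact test, adjusted p = 0.0126), led by sec-61.G (216.4) and sec-61.B (211.4) of the translocation channel. The rab family of small GTPases of vesicle traffic had 5 of 19 (26.3%, adjusted exact p = 0.0126), led by rab-7 of late endosomes (145.0) and rab-18 (102.4). Nuclear pore genes of the npp family had 5 of 26 (19.2%, adjusted exact p = 0.0390), led by npp-6 (153.6) and npp-3 (106.2). The vps family, also of vesicle traffic, did not pass with all its members (3 of 31, adjusted exact p = 0.671).

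With all members counted, the set family of putative histone methyltransferases also passed (5 of 31, 16.1%, adjusted exact p = 0.0484), as did the lin family, which shares a lineage phenotype and not a function (7 of 47, 14.9%, adjusted exact p = 0.0209). Neither passed without its members in the fixed lists (2 of 26, adjusted exact p = 1, and 4 of 30, adjusted exact p = 0.26).

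Motifs differed in where they passed. Summits near a tRNA gene were a class of their own here, so the promoter class held 496 summits, without 26 near a tRNA gene. TTTCGCG was found at 9.88% of summits in promoter windows against 2.52% of their flanks (adjusted Fisher p = 5.69e-09), and at 2.81% against 3.16% elsewhere (adjusted p = 0.766). CGCGCG was found at 10.9% against 1.11% in promoter windows and at 1.48% against 1.48% near tRNA genes, with 6.68% against 1.41% elsewhere (adjusted Fisher's exact p = 4.66e-08). TGACTCA was found at 2.22% against 0.706% in promoter windows (adjusted Fisher's exact p = 0.0227), and it did not pass near tRNA genes or elsewhere. GAGAGA passed in promoter windows (33.9%), near tRNA genes (37.0%) and elsewhere (34.1%). The differences between these classes of peaks were not tested. Over all 2080 6-mers, 652 were more frequent and 516 less frequent at summits than in flanks, with no allowance for GC content.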
